A study of Mus musculus with 39 samples.

How the data were processed

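Per the labels' protocols, microglia were sorted by flow cytometry from mice of 9 months and 3 ng of RNA was amplified with a Smart-seq v4 kit (Clontech). Libraries were made from 1 ng of cDNA with Nextera XT, and 3 indexed libraries were run per lane. The labels say that samples of each genotype were pooled for sequencing but do not assign samples to lanes, so genotype and lane cannot be separated here and no lane entered a fit. The submitters' processing notes name FastQC, STAR, HOMER, DESeq2 and limma and the mouse genome build mm10, without saying how each was used, and settings and the annotation are not given in the sources used here.

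The deposited expression values were log2 units as read here: the authors normalized and log-transformed them and, per the sheet name, applied surrogate variable analysis, and the log base is not given in the sources used here. Base 2 was taken because a natural log would imply back-transformed library totals many times higher than base 2 does. Sequencing depth could not be read from these values. The table held 10915 entries with 10914 distinct symbols, of which 10636 occurred among current reference names; 16 symbols had been turned into dates and were kept as entries but not named. The table also held 1 column that no sample label matched, and it was not used. All 39 labelled libraries had a column, and no pair of libraries was identical (within-group correlations 0.999158 to 0.99965).

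The second deposited table held, for 13624 genes, co-expression results by the authors. Its score columns, per the file headers, are the correlation of each gene with a trait and with each module, its p-value columns are unadjusted p-values by the authors that match correlations over 39 samples, and a further deposited column gives the module name of each gene. Of these genes 10907 were in the expression table. There were 9 named modules, and 3544 genes without one were left out. The deposited trait correlations followed the correlation with APP23 1xLPS membership (r = 0.986 across genes) more closely than that with any 1xLPS (0.519) or with the APP23 genotype (0.624).

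Each gene was fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 6 groups over all 39 libraries, empirical Bayes moderation with a mean-variance trend, and 11 contrasts: 9 between pairs of groups and 2 interactions. P-values were adjusted by the Benjamini-Hochberg method over the 10915 entries of each contrast, and adjusted p under 0.05 was called. No low-value filter and no pseudocount was applied. Standard errors are those of limma, and ± values are standard deviations between libraries. The rank of the residuals around the 6 group means was 24, below the 33 counted; around a common mean it was 29, around 3 treatment means 27 and around 2 genotype means 28. The same fit with the 9 directions that held no residual variance as covariates was set beforehand as an alternative and left 24 degrees of freedom, and its counts are given for each contrast.

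The genes named were set by a rule. For a contrast of 2 groups these were the 6 largest rises and the 6 largest falls by log2 difference among genes with adjusted p under 0.05 and a mean level above the lower quartile, and for an interaction 4 each way, leaving out unnamed gene models. Added to these were up to 4 called members of each list by smallest p, and 15 genes regardless of result: Hif1a, Apoe, Trem2, Clec7a, Cst7, Itgax, P2ry12, Tmem119, Cx3cr1, Il1b, Tnf, Tlr4, Cd14, App and Thy1. Results of 1 gene that the rule names are not reported here. Genes in the weighing of explanations that this rule did not name were chosen after their values were seen. Coordinates are those of GENCODE M21 on GRCm38 (mm10), matched by symbol, and count from 1. Reads shared between near-identical genes, such as the MHC class I genes and the zinc finger family, could be split in a way not given in the sources used here, so values of single members of these families are uncertain. Some glycolysis and ribosomal genes had low values, such as Pgam1 (4.22) and Gapdh (6.45) in wildtype PBS and Rpl19 (mean 4.41). Others did not, such as Aldoa (10.53 in wildtype PBS). Why was not tested, and results that rest on the low members of these lists are uncertain too.

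In all 29 gene lists were fixed: homeostatic microglia, plaque- or disease-associated microglia, HIF-1 targets, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, inflammatory cytokines and NF-kB targets, tolerance regulators, Toll-like receptor signalling, type I interferon response, antigen presentation, complement, phagocytic receptors, lysosome, cholesterol and lipid handling, TGF-beta, Rap1 and mTOR signalling, cytosolic ribosomal proteins, proliferation, immediate early and dissociation response, and markers of 8 groups of other cells. The 28 with measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a contrast, and again with the correlation estimated from the residuals, and with fry. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move one way on balance. Module scores were the mean over a module's genes of values standardized per gene, compared between groups by an exact two-sided permutation of the group means and adjusted over the 9 modules of each contrast. Overlap of lists with modules was tested by Fisher's exact test, adjusted over all pairs.

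The procedure was first run on simulated tables of 10915 independent genes, of which 100 were changed by 0.1 log2 and another 100 by 0.2. For wildtype 4xLPS against PBS without removed variation it recovered 69% and 97% with 1.78% of calls false. With 9 simulated factors removed while group means were kept, 83% and 100% were recovered with 33 degrees of freedom (40.4% false), and 77% and 99% with 24 (9.28% false). For APP23 4xLPS against PBS the corresponding recoveries were 61% and 95% (2.5% false), 70% and 99% (49.2% false), and 45% and 98% (15.4% false).

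Alternatives set beforehand were only the genes above the median mean level, quantile normalization, no variance trend, a replicate block, the 9 directions as covariates, only the groups of a contrast, leaving out each library of the APP23 LPS groups, the list and module variants above, module scores by the median or from genes with membership of 0.8 or more, and split controls for the correlations between contrasts. Camera with the 9 directions was added after seeing the data, as were the correlations of wildtype LPS contrasts with the genotype contrast. Correlations between contrasts that share controls were set beside 100 simulations of unchanged groups, in which the overlap of lists of the observed sizes, taken by smallest p in each direction, was added after seeing the data. Split controls were also simulated, after seeing the data, from residual libraries redrawn 100 times with the correlation between genes kept, with and without replacement, and with and without 9 random factors removed while group means were kept. The draws without replacement and with group means kept were repeated in 4 further sets. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.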

Results

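The study asked whether an immune challenge leaves a lasting trace in microglia, the resident macrophages of the brain, and whether that trace differs in an amyloid model. Female C57BL/6J mice were either APP23 hemizygotes, which carry a mutant human amyloid precursor protein (APP) transgene driven by Thy-1 and deposit amyloid plaques with age, or their wildtype littermates. At 3 months of age they were randomly given 4 daily intraperitoneal injections of vehicle (PBS), 1 injection of bacterial lipopolysaccharide (LPS) followed by 3 of vehicle (1xLPS), or 4 of LPS (4xLPS), each at 500 µg/kg. Microglia were sorted at 9 months and their polyadenylated RNA was sequenced. The 39 libraries comprised 9 wildtype PBS, 9 wildtype 1xLPS, 6 wildtype 4xLPS, 6 APP23 PBS, 5 APP23 1xLPS and 4 APP23 4xLPS. The labels number the libraries of a group without saying that each came from a different mouse, so p-values measure the spread between these libraries, which can be partly technical.

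The deposited values were corrected log expression values, read here as log2, for 10915 gene entries. They ran from 3.46 to 13.8, and the library means lay between 9.00 and 9.01, so sequencing depth was unknown. Differences between groups were small throughout on the scale of these corrected values. The largest among the called genes of all contrasts was 0.41 on the log2 scale, a 1.33-fold difference in Spp1. The median residual standard deviation over genes was 0.041. How the authors' normalization and correction scaled differences is not given in the sources used here. All folds are therefore those of the corrected values and can differ from folds in RNA level. Residuals around the 6 group means spanned 24 independent directions, not the 33 that 39 libraries allow, and permuting the labels 100 times never left fewer than 29. Variation in 9 directions had thus been removed from the table while the 6 group means were kept. Each contrast was therefore tested in limma with 33 residual degrees of freedom, as fixed before the data were examined, and with the 9 missing directions as covariates, which left 24. Genes are said to have risen or fallen where the adjusted p was under 0.05 with 33 degrees of freedom, and each comparison states which of its named genes also passed with 24. Tables of independent genes were simulated, with 100 genes changed by 0.1 log2 and another 100 by 0.2. After removal of 9 random factors with group means kept, 40.4% of the calls between wildtype 4xLPS and PBS were false with 33 degrees of freedom and 9.28% with 24. For APP23 4xLPS against PBS these shares were 49.2% and 15.4%. They depend on the number of genes changed and on genes being independent, so they do not give the share of false calls in the deposited table.

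**Figure D1:**
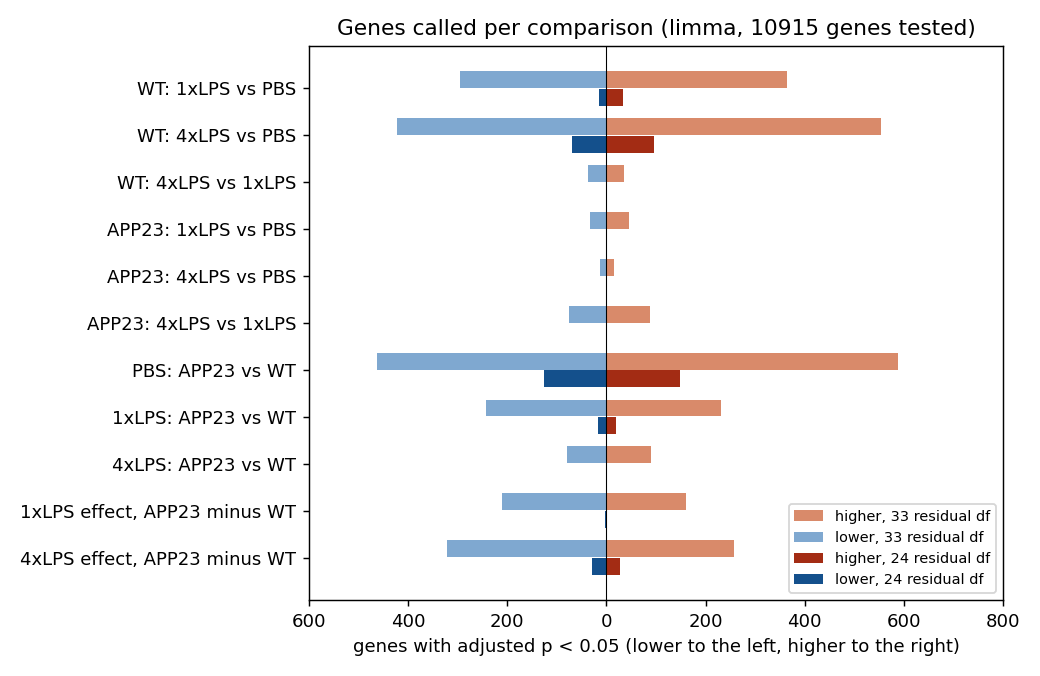
Number of genes higher or lower (horizontal axis) in each contrast (vertical axis) at an adjusted p under 0.05, with 33 residual degrees of freedom and with 24. The contrast of APP23 with wildtype PBS microglia had the most calls in both fits, 1050 and 274, and the contrasts within APP23 and that of the genotypes after 4xLPS had 0 with 24.

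In wildtype mice, a single LPS injection was followed by higher Zfp408, a zinc finger gene, and by lower Lpl, the lipoprotein lipase of plaque-associated microglia. Zfp408 (chromosome 2, 91643669 to 91649791, minus strand) rose from 9.18 ± 0.052 to 9.38 ± 0.055 (SD, n = 9 each), a log2 difference of 0.20 (SE 0.028, adjusted p = 7.82e-05), and was above the PBS mean in 9 of 9 libraries. Lpl (chromosome 8, 68880491 to 68907448, plus strand) fell from 9.396 ± 0.076 to 9.19 ± 0.096, a difference of -0.21 (SE 0.055, adjusted p = 0.0241). It was below the PBS mean in 9 of 9 libraries but did not pass with 24 degrees of freedom (adjusted p = 0.128). Psap, the precursor of the lysosomal saposins (chromosome 10, 60277627 to 60302597, plus strand), rose by 0.10 (SE 0.0155, adjusted p = 0.000273), in 9 of 9 libraries. Tlr4, the receptor for LPS, fell by 0.055 (SE 0.012, adjusted p = 0.00795), in 9 of 9 libraries, a call lost with 24 degrees of freedom (adjusted p = 0.0794). Other large rises were in Zfp26 (0.17), the clock gene Per1 (0.17), Prdm15 (0.17), Sdr42e1 (0.14) and Zfp867 (0.13). The largest falls after Lpl were in Wdr62 (-0.155), Zfp783 (-0.155), the cAMP phosphodiesterase Pde4b (-0.14), Pdp1 (-0.13) and Zfp229 (-0.125). Of the genes in this paragraph Zfp408, Zfp26, Sdr42e1, Psap and Wdr62 passed with 24 degrees of freedom; the adjusted p of the others there ran from 0.063 for Pde4b to 0.133 for Zfp867.

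Homeostatic microglia genes moved upward as a group after 1xLPS in wildtype mice: 17 of the 20 measured had positive differences (median 0.028), and limma's camera gave an adjusted p = 0.00866, against an adjusted p = 0.818 with an estimated correlation. Only Rhob, a small GTPase (0.065), rose over all genes and 2 rose adjusted over the list alone, while P2ry12 (0.034), Tmem119 (0.048) and Cx3cr1 (0.029) did not pass. Of 25 plaque- or disease-associated genes, the adaptor Tyrobp rose (0.066) and Lpl, Ank (-0.092) and the growth factor Csf1 (-0.10) fell, with 1 higher and 4 lower adjusted over the list alone. Among 18 cholesterol and lipid genes 4 fell, namely Lpl, the lipid droplet coat Plin2 (-0.048), the desaturase Scd2 (-0.058) and the sterol synthesis enzyme Hmgcs1 (-0.078), with 4 adjusted over the list alone (camera adjusted p = 0.085). Of 41 nuclear-encoded oxidative phosphorylation genes 5 rose, including Ndufs7 (0.039) and Cox7b (0.0395), and 7 adjusted over the list alone (camera adjusted p = 0.085). Of 35 lysosomal genes 3 rose, with Psap and Hexa (0.0355) among them, and the acid lipase Lipa fell (-0.035), against 7 and 3 adjusted over the list alone (camera adjusted p = 0.0817). The phagocytic receptors held 4 risers of 20, including the Fc receptors Fcgr1 (0.035) and Fcgr2b (0.037), with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.338). In the Toll-like receptor list of 28, Chuk, a kinase of the NF-kB pathway, rose (0.051) and Tlr4 and Tlr6 (-0.058) fell, with 1 higher and 4 lower adjusted over the list alone. The median of this list was 0.0011, its mean -0.0018 and its test pointed down (camera adjusted p = 0.668). In all, 365 genes rose and 295 fell, of which 33 and 15 passed with 24 degrees of freedom, and of the genes named from lists only Psap did. Of 14 complement genes 0 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 0.338).

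After 4xLPS in wildtype mice Lpl and the chemokine genes Ccl3 and Ccl4 fell, while complement C3 rose. Lpl reached 9.08 ± 0.10 (n = 6), a difference of -0.32 from PBS (SE 0.062, adjusted p = 0.00157), and was below the PBS mean in 6 of 6 libraries. The chemokines Ccl4 (-0.17, SE 0.029, adjusted p = 0.000458) and Ccl3 (-0.11, SE 0.022, adjusted p = 0.00173) fell in 6 of 6. So did Dock9, an exchange factor for Cdc42 (-0.17, SE 0.021, adjusted p = 3.09e-06; chromosome 14, 121542046 to 121797837, minus strand). C3 (chromosome 17, 57203970 to 57228136, minus strand) rose from 6.705 ± 0.105 to 6.92 ± 0.087, a difference of 0.21 (SE 0.047, adjusted p = 0.00425), in 6 of 6. No other of the 14 complement genes passed over all genes or adjusted over the list alone. Sdr42e1 (chromosome 8, 117661399 to 117673689, minus strand) showed the largest rise, from 8.18 ± 0.062 to 8.43 ± 0.032, or 0.24 (SE 0.029, adjusted p = 3.09e-06). All of these passed with 24 degrees of freedom. Kbtbd8 (0.19), Zfp738 (0.18), G2e3 (0.18), Per1 (0.17) and Zfp456 (0.17) also rose, and Gltscr1 (-0.20), Zmat1 (-0.18) and the phagocytic receptor Axl (-0.16) fell; among these Per1 (adjusted p = 0.0816), Zmat1 (0.0914) and Axl (0.106) did not pass with 24.

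Among the lists, 3 of 25 plaque- or disease-associated genes fell after 4xLPS in wildtype mice, namely Lpl, Axl and the lectin receptor Clec7a (-0.125), with 3 higher and 4 lower adjusted over the list alone. Both members of the 18 inflammatory genes that passed, Ccl3 and Ccl4, fell, with 5 lower adjusted over the list alone (camera adjusted p = 0.0621). Cholesterol genes fell in 3 of 18, among them Hmgcs1 (-0.11) and the sterol regulator Srebf2 (-0.080), with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0874). In the interferon list 2 of 24 fell, Stat2 (-0.073) and Mx1 (-0.115), with 4 lower adjusted over the list alone (camera adjusted p = 0.273). The MHC class II chain H2-Aa fell by 0.14 (adjusted p = 0.0358, and 0.133 with 24 degrees of freedom), the only member of the 18 antigen presentation genes to pass over all genes or adjusted over the list alone. Of 18 HIF-1 genes 3 fell, including Arnt (-0.066) and the glucose transporter Slc2a1 (-0.059), with 1 higher and 4 lower adjusted over the list alone; the list's median was 0.015 and its mean 0.0034, while its test pointed down (camera adjusted p = 0.736). Ribosomal protein genes held 6 risers and 1 faller of 49, including Rpl19 (0.019) and Rpl22 (0.0925), the same numbers as adjusted over the list alone (camera adjusted p = 0.311). The mean level of Rpl19, 4.41, was near the lowest value of all genes, 3.46. Rhob (0.088) and Psap (0.0735) rose, the only ones of 20 homeostatic and 35 lysosomal genes over all genes or adjusted over the list alone. Of 28 Toll-like receptor genes Chuk (0.079) rose and Tlr4 (-0.0465) fell, the same numbers as adjusted over the list alone. With 24 degrees of freedom the list genes that passed were Lpl, C3, Ccl3, Ccl4, Chuk, Rhob and Rpl19, and Psap had an adjusted p = 0.0589. In total 554 genes rose and 423 fell, of which 96 and 69 passed with 24 degrees of freedom. No list passed camera (smallest adjusted p = 0.0621).

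**Figure D2:**
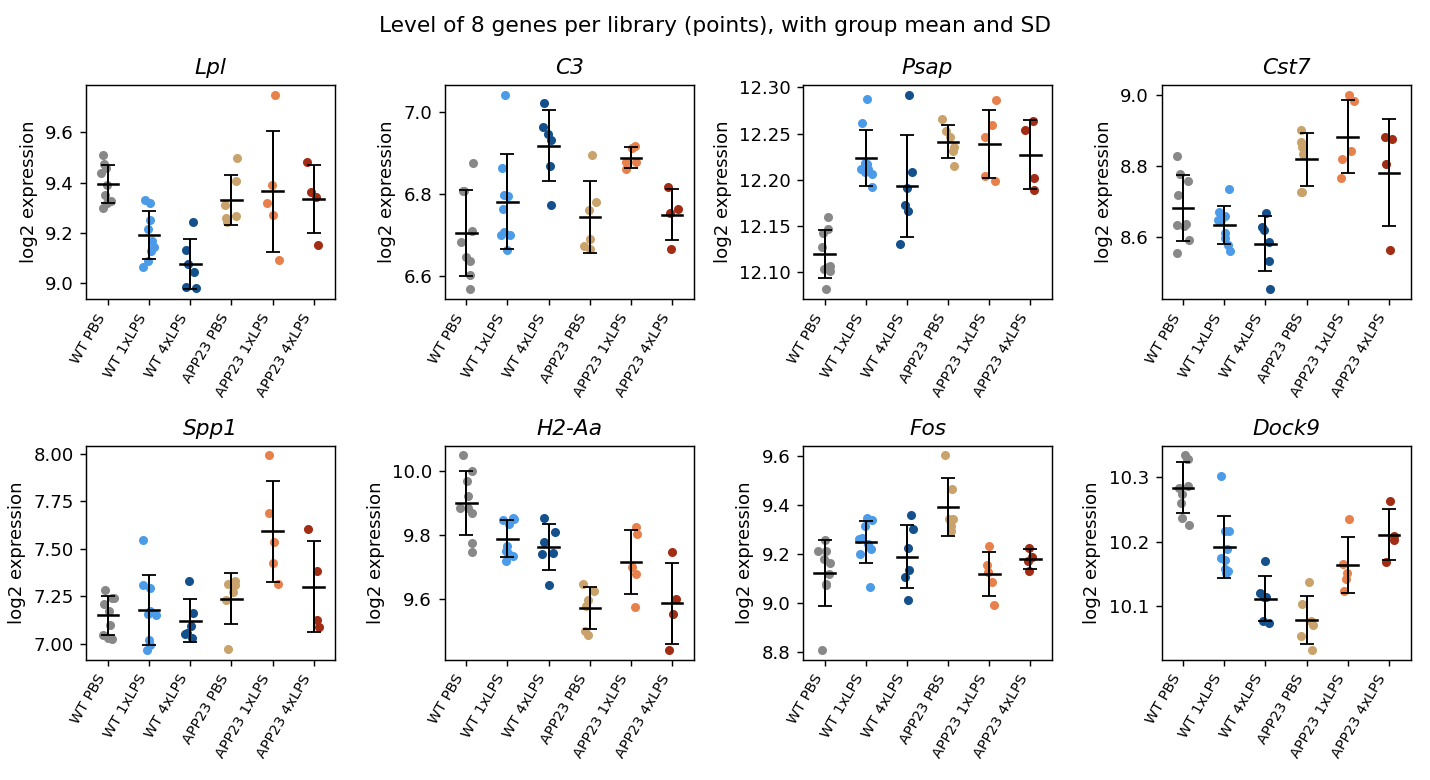
Corrected log2 expression (vertical axis) of Lpl, C3, Psap, Cst7, Spp1, H2-Aa, Fos and Dock9 in each library of the 6 groups, with points for libraries and bars for the group mean and SD. Lpl falls from a mean of 9.396 in wildtype PBS to 9.08 after 4xLPS, and H2-Aa is at 9.90 in wildtype PBS and 9.57 in APP23 PBS.

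Set directly against each other, 4 and 1 LPS injections in wildtype mice left fewer differences. The kinase gene Hipk2 (chromosome 6, 38694390 to 38876165, minus strand) was lower after 4xLPS, at 8.81 ± 0.069 (n = 6) against 8.99 ± 0.055 (n = 9), a difference of -0.17 (SE 0.030, adjusted p = 0.00229). St7l (chromosome 3, 104864005 to 104930064, plus strand) was lower by a difference of -0.12 (SE 0.020, adjusted p = 0.00202). Each lay below the 1xLPS mean in 6 of 6 libraries and missed the threshold with 24 degrees of freedom (adjusted p = 0.0531 for both). Ccl4 was lower after 4xLPS too (-0.12, adjusted p = 0.0438; 0.292 with 24 degrees of freedom), the only one of 18 inflammatory genes to pass, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.133). Asb1 (-0.16), Zfp408 (-0.13) and Gltscr1 (-0.12) were also lower, and Fam120c (0.16), Zfp595 (0.15), Kbtbd8 (0.13), Ranbp6 (0.13), Ubn1 (0.13) and Ermap (0.12) higher. From the lists, Magi1, a Rap1 pathway scaffold (0.12), and Rpl19 (0.019, at a low mean level of 4.41) were higher, with 1 Rap1 gene of 21 and 2 ribosomal genes of 49 higher adjusted over the list alone. The counts were 35 higher and 37 lower, of which 1 and 1 passed with 24 degrees of freedom, neither of them named here. No list passed camera (smallest adjusted p = 0.107, for the interferon list).

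Among mice given PBS, APP23 microglia had lower H2-Aa, H2-Eb1, H2-Ab1 and Cd74, genes of MHC class II presentation, and higher Fos and Per1 than wildtype microglia. H2-Aa (chromosome 17, 34282744 to 34287823, minus strand) was at 9.57 ± 0.065 (n = 6) against 9.90 ± 0.099 (n = 9), a difference of -0.33 or 0.797-fold (SE 0.043, adjusted p = 1.37e-05). H2-Eb1 (-0.29, adjusted p = 5.08e-05), H2-Ab1 (-0.27, adjusted p = 0.000113) and the invariant chain Cd74 (-0.26, adjusted p = 9.86e-05; chromosome 18, 60803848 to 60812652, plus strand) were lower as well, each in 6 of 6 libraries. Fos (chromosome 12, 85473890 to 85477273, plus strand), an AP-1 subunit induced within minutes of stimulation, was higher by 0.27 (SE 0.054, adjusted p = 0.00174), and Per1 by 0.205 (SE 0.044, adjusted p = 0.00299), in 6 of 6. The transcription factor Klf10 (chromosome 15, 38291463 to 38300706, minus strand) was lower, at 9.15 ± 0.045 against 9.38 ± 0.041, a difference of -0.23 (SE 0.025, adjusted p = 2.68e-07). All of these passed with 24 degrees of freedom. Of 8 dendritic cell markers 7 had negative differences (mean -0.0423, exact p = 0.0412, adjusted p = 0.0823). Ccr2, a chemokine receptor and monocyte marker, was lower (-0.23, adjusted p = 0.00303), the only one of 5 measured monocyte and neutrophil genes to pass, with 2 lower adjusted over the list alone. Stab1, a receptor counted among macrophage markers, was higher (0.067, adjusted p = 0.00335), the only one of 7 such markers to pass over all genes or adjusted over the list alone. Col6a3 (0.21), Tbc1d32 (0.19), Atp11a (0.19) and Mapkbp1 (0.18) completed the largest rises, and all but Atp11a (adjusted p = 0.0561) passed with 24 degrees of freedom, as did Ccr2 and Stab1.

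Of the 18 antigen presentation genes in this comparison 1 was higher and 5 lower, the same numbers as adjusted over the list alone, with a median of -0.0013, a mean of -0.063 and a camera adjusted p = 0.0542. Immediate early genes were higher as a group, with 4 of 18 higher and 1 lower and, adjusted over the list alone, 6 and 1 (camera adjusted p = 0.0495; adjusted p = 0.784 with an estimated correlation). Besides Fos these included the phosphatase Dusp1 (0.15) and Klf2 (0.063). Homeostatic genes were higher as a group, 19 of 20 with positive differences (camera adjusted p = 0.0495; adjusted p = 0.784 with an estimated correlation), although only Rhob (0.11) passed over all genes or adjusted over the list alone. Phagocytic receptors held 6 higher and 1 lower of 20, including the efferocytosis receptor Mertk (0.033) and Scarb2 (0.064), and 8 and 1 adjusted over the list alone (camera adjusted p = 0.0586). In the interferon list 4 of 24 were higher, with Oas1a (0.064) and the sensor Zbp1 (0.13) among them, and 5 adjusted over the list alone (camera adjusted p = 0.0542). Psap was higher (0.12, adjusted p = 5.08e-05), the only one of 35 lysosomal genes to pass over all genes or adjusted over the list alone. Plaque- or disease-associated genes were higher in 2 of 25, Cst7 (0.14) and Tyrobp (0.051), the same number as adjusted over the list alone, and Apoe differed by 0.092 without passing (adjusted p = 0.09). Of 18 HIF-1 genes 3 were higher, the stress gene Ddit4 (0.18) and the prolyl hydroxylase Egln1 (0.11) among them, and 1 lower, with 3 and 4 adjusted over the list alone. Of 19 glycolysis genes the hexokinase Hk2 (0.073) was higher and the glucose transporter Slc2a3 (-0.14) lower, with 1 and 3 adjusted over the list alone. Of 18 inflammatory genes 1 was higher and the cytokine Il1a (-0.060) lower, the same numbers as adjusted over the list alone. Of 28 Toll-like receptor genes 2 were higher, Chuk (0.064) among them, and Tlr4 (-0.065) and Tlr2 (-0.057) lower, the same numbers as adjusted over the list alone. Of 26 mTOR genes 3 were higher, with Mtor (0.11) among them, and 1 lower, with 4 and 2 adjusted over the list alone. Altogether 587 genes were higher and 463 lower, of which 148 and 126 passed with 24 degrees of freedom. Of the list genes in this paragraph those kept there were Fos, Rhob, Mertk, Scarb2, Psap, Ddit4, Egln1, Hk2, Chuk, Il1a and Tlr4, while Cst7 (adjusted p = 0.14), Tyrobp (0.139) and Dusp1 (0.106) were lost.

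In APP23 mice a single LPS injection was followed by higher H2-D1 and H2-K1, genes of MHC class I, and lower Fos. H2-D1 (chromosome 17, 35262730 to 35267499, plus strand) rose from 11.08 ± 0.030 (n = 6) to 11.17 ± 0.0425 (n = 5), a difference of 0.089 (SE 0.018, adjusted p = 0.0128). H2-K1 rose by 0.074 (SE 0.017, adjusted p = 0.0329), each in 5 of 5 libraries. Antigen presentation genes moved upward as a group, with 16 of 18 positive (median 0.043), 2 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 3.82e-07; adjusted p = 0.168 with an estimated correlation). Fos fell, a difference of -0.275 (SE 0.0625, adjusted p = 0.0302). The immediate early list moved downward, with 1 of 18 lower over all genes and 4 adjusted over the list alone (median -0.050, camera adjusted p = 0.00022; adjusted p = 0.168 with an estimated correlation). Lysosomal genes (camera adjusted p = 0.0174; adjusted p = 0.475 with an estimated correlation) moved upward, with 0 of 35 over all genes or adjusted over the list alone. Ribosomal genes (camera adjusted p = 0.0274; adjusted p = 0.425 with an estimated correlation) moved downward, with 0 of 49 over all genes and 3 adjusted over the list alone. Als2cl (chromosome 9, 110879870 to 110900530, plus strand) rose from 8.225 ± 0.040 to 8.46 ± 0.091, by 0.23 (SE 0.044, adjusted p = 0.00786). Senp8, a protease of NEDD8 (chromosome 9, 59734259 to 59750710, minus strand), fell from 9.498 ± 0.033 to 9.33 ± 0.025, a difference of -0.17 (SE 0.0265, adjusted p = 0.00183). Kctd12b (0.22), Fgl2 (0.20), Sema4a (0.16), Napb (0.15) and Dstyk (0.15) rose, and Kcnj2 (-0.19), Osbpl3 (-0.16), Mtor (-0.15), Ncoa2 (-0.125) and Ccl3 (-0.11) fell. Mtor was the only one of 26 mTOR genes over all genes, with 1 higher and 1 lower adjusted over the list alone, and Ccl3 the only one of 18 inflammatory genes, with 3 lower. The integrin Itgax differed by 0.15 without passing (adjusted p = 0.0886).

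This comparison called 45 genes higher and 33 lower with 33 degrees of freedom, and limma called 0 of the 10915 with 24, where 924 had an unadjusted p under 0.05; the smallest adjusted p among the named genes was 0.0709, for Senp8. Leaving out APP23 1xLPS replicate 1, 2, 3 or 4 gave 23, 39, 29 and 38 calls in place of 78, and of the named genes only Als2cl, Senp8 and Ncoa2 passed with each single library left out.

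After 4xLPS in APP23 mice few genes passed. Dock9 rose from 10.08 ± 0.037 (n = 6) to 10.21 ± 0.039 (n = 4), by 0.13 (SE 0.026, adjusted p = 0.0279), and the sialyltransferase gene St8sia4 from 9.18 ± 0.085 to 9.37 ± 0.060, by 0.19 (SE 0.044, adjusted p = 0.047). Ctsh, a lysosomal cathepsin (chromosome 9, 90054152 to 90076089, plus strand), rose from 11.33 ± 0.011 to 11.39 ± 0.015, by 0.0575 (SE 0.011, adjusted p = 0.0279). No other of the 35 lysosomal genes passed over all genes or adjusted over the list alone. Fam199x (0.16), Wdr47 (0.155), Polr3d (0.13) and Pyurf (0.13) also rose, and Tmem110 (-0.14), the phosphofructokinase Pfkm (-0.14), Meis1 (-0.11), Rab3ip (-0.11), Patz1 (-0.10) and Hipk1 (-0.10) fell, each in 4 of 4 libraries. Interferon response genes moved downward as a group, 21 of 24 with negative differences (median -0.035), with 0 passing over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.000741; adjusted p = 0.948 with an estimated correlation). The counts were 15 higher and 12 lower, and limma called 0 with 24 degrees of freedom (each named gene at adjusted p = 0.39), where 832 had an unadjusted p under 0.05. No named gene passed with every single library left out. The 27 calls became 9, 8 and 11 without APP23 1xLPS replicates 1, 2 and 4, which share the estimate of the spread, and 9, 11, 11 and 7 without 4xLPS replicates 1 to 4.

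Between 4xLPS and 1xLPS in APP23 mice 4 lists passed camera. Antigen presentation genes were lower after 4xLPS, 16 of 18 with negative differences (median -0.072). Over all genes 2 passed, H2-K1 (-0.081) and the peptide transporter Tap1 (-0.10), and 8 adjusted over the list alone (camera adjusted p = 9.22e-07; adjusted p = 0.399 with an estimated correlation). Interferon genes were lower, with 21 of 24 negative (median -0.0405), 1 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 6.33e-05; adjusted p = 0.44 with an estimated correlation). Plaque- or disease-associated genes were lower, 22 of 25 negative, with Timp2 (-0.049) the only one to pass over all genes or adjusted over the list alone. Immediate early genes were higher, 17 of 18 positive with 0 passing over all genes or adjusted over the list alone (for both lists, camera adjusted p = 0.0146 and adjusted p = 0.465 with an estimated correlation). Stag3, a cohesin subunit (chromosome 5, 138280240 to 138312393, plus strand), was lower after 4xLPS, at 8.80 ± 0.089 (n = 4) against 9.09 ± 0.084 (n = 5), a difference of -0.29 (SE 0.056, adjusted p = 0.00586). Als2cl was lower by a difference of -0.24 (SE 0.049, adjusted p = 0.0117). Kcnj9 (0.20), Slc5a3 (0.195), Zfp229 (0.18), Wdr62 (0.18), Slc27a4 (0.16), Zfp346 (0.16) and Nrros (0.0495) were higher, and Sdc3 (-0.19), Sptbn1 (-0.18), Ylpm1 (-0.17), Cdc27 (-0.145), Pfkm (-0.13), Scd2 (-0.087) and Tgfbr2 (-0.040) lower. Aqp4, an astrocyte water channel, was higher (0.088, adjusted p = 0.0166), with 1 of 4 measured astrocyte genes higher over all genes and 1 higher and 1 lower adjusted over the list alone. Of 162 calls, 87 higher and 75 lower, limma kept 0 with 24 degrees of freedom, where 1063 genes had an unadjusted p under 0.05. Their number was 60, 84, 86 and 49 without APP23 1xLPS replicates 1 to 4 and 103, 71 and 65 without 4xLPS replicates 1 to 3, and Stag3, Als2cl, Ylpm1 and Cdc27 passed with each single library left out.

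After 1xLPS, APP23 microglia had higher Spp1 and Cst7, genes of plaque-associated microglia, than wildtype microglia. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050, plus strand), was at 7.59 ± 0.26 (n = 5) against 7.18 ± 0.18 (n = 9), a difference of 0.41 or 1.33-fold (SE 0.090, adjusted p = 0.00657; 0.069 with 24 degrees of freedom), in 5 of 5 libraries. Cst7, which encodes cystatin F (chromosome 2, 150570415 to 150578944, plus strand), was at 8.88 ± 0.10 against 8.635 ± 0.0535, a difference of 0.25 (SE 0.047, adjusted p = 0.00248; 0.0426 with 24 degrees of freedom). The list of 25 was higher as a group, 21 positive (median 0.040). It had 4 higher, Timp2 (0.052) among them, 1 lower (the adhesion molecule Cadm1, -0.070), and 7 and 1 adjusted over the list alone (camera adjusted p = 0.000511; adjusted p = 0.388 with an estimated correlation). Interferon genes were higher, with 3 of 24 passing, Rtp4 (0.093) and Irf9 (0.049) among them, and 3 adjusted over the list alone (camera adjusted p = 0.00888; adjusted p = 0.659 with an estimated correlation). Lysosomal genes were higher, with 4 of 35 passing, Scpep1 (0.049), the cathepsin Ctsl (0.051), Lamp1 (0.034) and Npc2 (0.035), and 4 adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.659 with an estimated correlation). MHC class I H2-K1 (0.095, adjusted p = 0.000895) and H2-D1 (0.0965, adjusted p = 0.00138) and their regulator Nlrc5 (0.18) were higher and H2-DMa lower (-0.0415), with 5 higher and 1 lower of 18 adjusted over the list alone (camera adjusted p = 0.0706). Scd2 (0.10) and the sterol exporter Abcg1 (0.11) were higher among 18 cholesterol genes, 5 adjusted over the list alone (camera adjusted p = 0.0706).

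The macrophage mannose receptor Mrc1, a marker of perivascular macrophages (chromosome 2, 14229392 to 14332057, plus strand), was lower in APP23 than in wildtype microglia after 1xLPS, a difference of -0.21 (SE 0.055, adjusted p = 0.021). Maf from the same list was higher (0.047, adjusted p = 0.048), with 1 higher and 3 lower of 7 adjusted over the list alone. Stag3 (0.22), Xrcc2 (0.19), Adam22 (0.16) and Zkscan5 (0.16) were also higher, and Cep97 (-0.20), Kcnj9 (-0.17), Wdr4 (-0.17), Ndst1 (-0.16), Banp (-0.155) and Il1a (-0.059) lower. Il1a was the only one of 18 inflammatory genes to pass over all genes or adjusted over the list alone. Of 231 higher and 243 lower genes, 19 and 17 passed with 24 degrees of freedom, and of those named Cst7, H2-K1, H2-D1, Scd2, Zkscan5, Wdr4 and Ndst1 did (Mrc1 adjusted p = 0.123). The number of calls was 262, 272 and 238 without APP23 1xLPS replicates 1, 2 and 4, and 16 of the 28 named genes that passed did so with each single library left out, Spp1 and Cst7 included.

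After 4xLPS fewer genes were called between the genotypes. This contrast had 4 and 6 libraries, against 6 and 9 in PBS, so its lower count does not show a smaller difference. Dnajb1, a heat shock cochaperone (chromosome 8, 83608193 to 83612653, plus strand), was higher in APP23, at 10.46 ± 0.034 (n = 4) against 10.35 ± 0.010 (n = 6), a difference of 0.11 (SE 0.018, adjusted p = 0.00211), in 4 of 4 libraries. Klf2 was higher by 0.0825, and these were the 2 of 18 immediate early genes that passed over all genes and adjusted over the list alone (camera adjusted p = 0.207). Zfp169 was at 8.90 ± 0.051 against 9.16 ± 0.089, a difference of -0.26 (SE 0.0585, adjusted p = 0.0206). The class II chain H2-Eb1 was lower by a difference of -0.20 (SE 0.051, adjusted p = 0.04). It was the only one of 18 antigen presentation genes to pass, with 4 lower adjusted over the list alone (camera adjusted p = 0.207). Ms4a7, a macrophage marker, was lower (-0.18, adjusted p = 0.0138), the only one of 7 such markers to pass over all genes or adjusted over the list alone. Cst7 was higher by 0.20 (adjusted p = 0.0483), above the wildtype mean in 3 of 4 libraries. It was the only one of 25 plaque- or disease-associated genes over all genes and 1 of 3 higher adjusted over the list alone, where 1 was lower (camera adjusted p = 0.546). Ctsh (0.051), Irak4 (0.081) and Ticam2 (0.064) were higher, the latter 2 of 28 Toll-like receptor genes passing over all genes and adjusted over the list alone, as were Phka1 (0.17), Synj2 (0.16), Fam196b (0.15), Ptrhd1 (0.15) and Fam199x (0.15). Lysmd4 (-0.16), Kremen1 (-0.15), Tmem110 (-0.14) and Prpf8 (-0.13) were lower. Of 91 higher and 80 lower genes limma kept 0 with 24 degrees of freedom, where 1041 had an unadjusted p under 0.05. Without APP23 4xLPS replicates 2, 3 and 4 the 171 calls numbered 71, 53 and 66, and Dnajb1, Kremen1 and Ms4a7 were the named genes that passed with each single library left out.

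Whether the response to LPS differed between genotypes was tested as an interaction, APP23 response minus wildtype response. This equals the genotype difference after LPS minus that in PBS, and both interactions use the same PBS groups. For 1xLPS, Fos had the largest difference, -0.40 (SE 0.079, adjusted p = 0.00471; 0.0664 with 24 degrees of freedom), with a fall in APP23 and a wildtype mean of 9.25 after 1xLPS against 9.12 in PBS. The MHC class II genes Cd74, H2-Aa and H2-Eb1 had the opposite sign, Cd74 at 0.26 (SE 0.058, adjusted p = 0.0127), H2-Aa at 0.25 (SE 0.062, adjusted p = 0.0203) and H2-Eb1 at 0.22 (adjusted p = 0.0365), as did H2-D1 (0.084), Als2cl (0.28) and Kctd12b (0.26). The antigen presentation list had 5 of 18 higher over all genes and 7 adjusted over the list alone (median 0.033, mean 0.083, camera adjusted p = 0.000202; adjusted p = 0.606 with an estimated correlation). The immediate early list had 1 higher and 1 lower of 18 over all genes and 1 and 5 adjusted over the list alone (median -0.081, camera adjusted p = 0.00153; adjusted p = 0.539 with an estimated correlation). Osbpl3 (-0.29), Xkr8 (-0.22), Fpgt (-0.21), Mtor (-0.19), Rhob (-0.11) and Psap (-0.11) had negative interactions. The counts of their lists were 2 negative of 26 mTOR genes, 1 negative of 20 homeostatic genes, and 2 positive and 1 negative of 35 lysosomal genes, the same as adjusted over the list alone. In PBS the genotypes differed with the opposite sign in Fos (0.27), Cd74 (-0.26), H2-Aa (-0.33), H2-Eb1 (-0.29), Mtor (0.11), Rhob (0.11) and Psap (0.12). For Cd74, Rhob and Psap this PBS difference nearly equalled the interaction in size, which leaves little genotype difference after 1xLPS. Psap had its lowest mean of all groups in wildtype PBS. The interaction test alone does not show whether the PBS or the LPS groups account for these interactions. The counts were 160 positive and 210 negative, 2 and 2 with 24 degrees of freedom (none of the named genes, Osbpl3 closest at adjusted p = 0.0626), and 223 and 222 in all without APP23 1xLPS replicate 1 or 4. Of 9 fits with 1 library left out the calls of H2-Eb1 and H2-D1 were lost in 3 and 2 (highest adjusted p = 0.0881). The other 11 named genes passed in each.

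For 4xLPS, Dock9 had the smallest p, an interaction of 0.30 (SE 0.033, adjusted p = 5.75e-07; 0.000155 with 24 degrees of freedom), since it fell in wildtype and rose in APP23 mice. Lpl had an interaction of 0.32 (SE 0.098, adjusted p = 0.0453; 0.18 with 24 degrees of freedom), and its call was lost without APP23 4xLPS replicate 1, 2 or 4 (highest adjusted p = 0.11). Of 9 fits with 1 library left out the calls of Fos, Zfp169, Srebf2 and Sqle were lost in 7, 6, 5 and 1 (highest adjusted p = 0.122). St8sia4 (0.28) and Mrc2 (0.28) were positive and Sdr42e1 (-0.27, adjusted p = 0.000794), Tmem110 (-0.25, adjusted p = 0.000609), Zfp169 (-0.25), Fos (-0.28) and Chuk (-0.10) negative. Cholesterol genes had positive interactions in 4 of 18, Lpl, Hmgcs1 (0.17), Sqle (0.14) and Srebf2 (0.12), with 4 adjusted over the list alone (camera adjusted p = 0.571). Ctsh was positive (0.067, adjusted p = 0.00517) and the macrophage marker Ms4a7 negative (-0.19, adjusted p = 0.016). The counts were 258 positive and 321 negative, 28 and 29 with 24 degrees of freedom (Dock9, St8sia4, Sdr42e1 and Tmem110 among them), and 365 in all without APP23 4xLPS replicate 3.

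**Figure D3:**
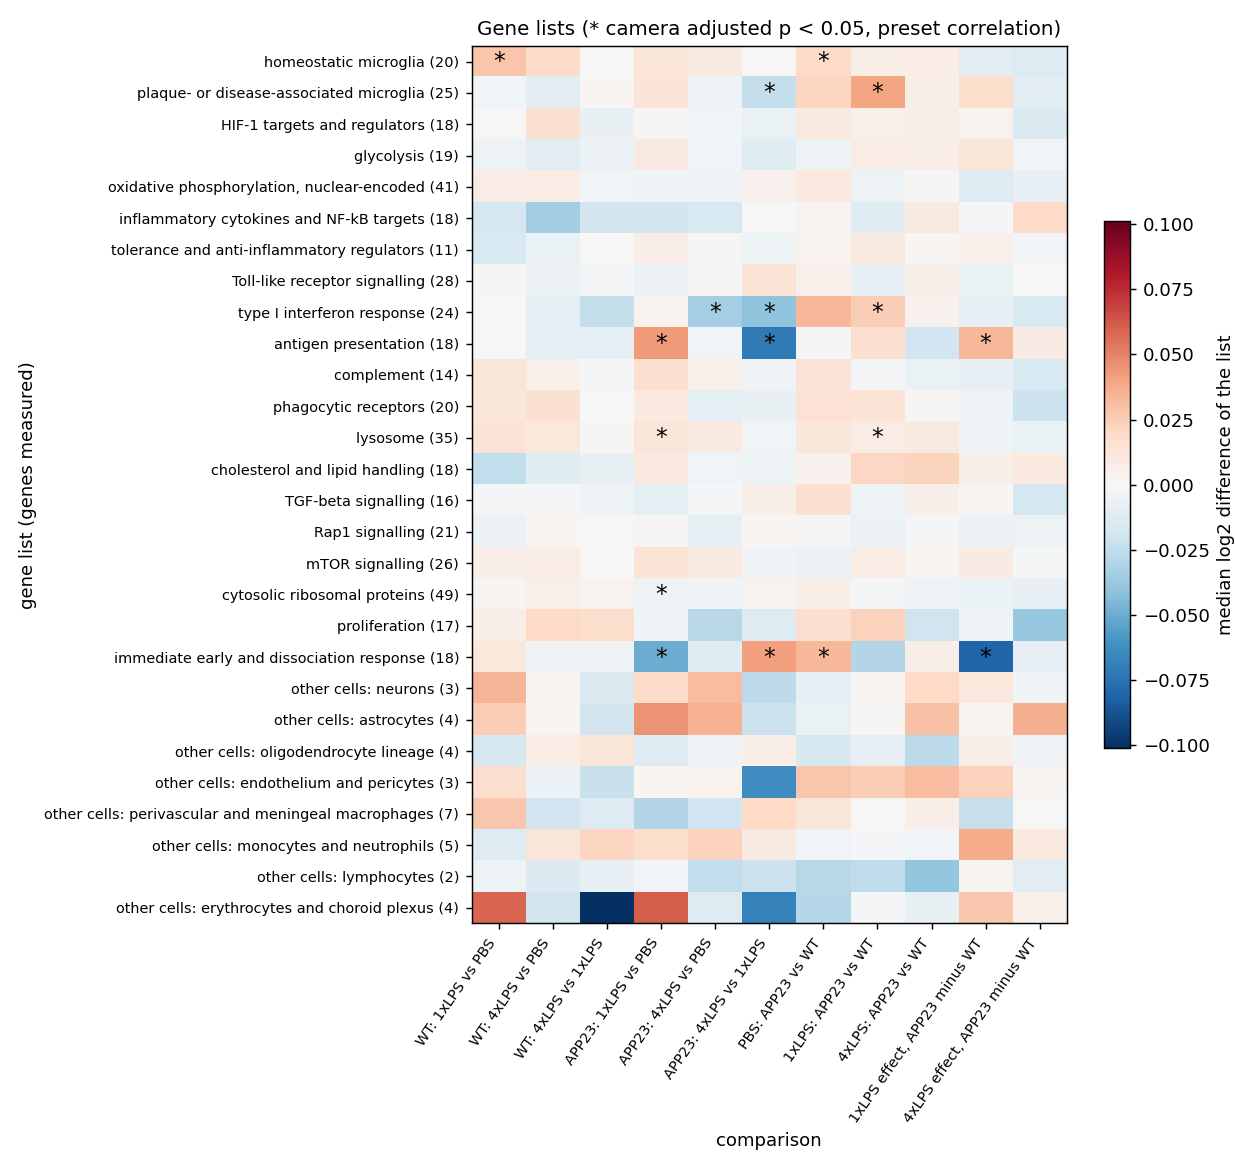
Median log2 difference (colour) of each gene list (vertical axis) in each contrast (horizontal axis), with an asterisk where camera gave an adjusted p under 0.05. Antigen presentation is at 0.043 for APP23 1xLPS against PBS and -0.072 for APP23 4xLPS against 1xLPS.

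Several gene groups fixed in advance passed camera in no contrast. The smallest adjusted p was 0.65 for HIF-1 targets, 0.0645 for glycolysis and for oxidative phosphorylation, 0.0621 for inflammatory genes, and 0.396 for tolerance regulators. It was 0.204 for Toll-like receptor signalling, 0.146 for complement, 0.0586 for phagocytic receptors, and 0.0706 for cholesterol and lipid handling. For signalling and growth it was 0.462 for TGF-beta signalling, 0.623 for Rap1 signalling, 0.481 for mTOR signalling and 0.208 for proliferation. Markers of other cells did not pass as groups either: neurons (0.417, 3 genes measured), astrocytes (0.324, 4), oligodendrocyte lineage (0.556, 4), endothelium and pericytes (0.424, 3), perivascular and meningeal macrophages (0.424, 7), monocytes and neutrophils (0.406, 5), lymphocytes (0.561, 2) and erythrocytes and choroid plexus (0.138, 4). None of the 13 mitochondrially encoded mRNAs was in the table. With an estimated correlation no list passed in any contrast (smallest adjusted p = 0.168).

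Of the genes chosen in advance for every contrast, P2ry12, Tmem119, Cx3cr1, Apoe, Trem2, Hif1a, Il1b, Tnf, Cd14 and Itgax passed in none. Hif1a came closest between the genotypes after 1xLPS, at 0.053 (adjusted p = 0.0548). The endogenous App gene fell after 1xLPS in wildtype mice by 0.034 (adjusted p = 0.0392; 0.176 with 24 degrees of freedom) and was not higher in APP23 PBS microglia (-0.012, adjusted p = 0.52). Thy1, whose promoter drives the transgene, was not in the table.

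The authors' co-expression modules were built on these 39 samples and so are not independent of the groups. Wildtype LPS contrasts with PBS and the genotype contrast in PBS share the wildtype PBS libraries, so their calls are not separate findings. Brown and pink scores were lowest in that group (-0.45 and -0.535), against 0.032 to 0.19 and -0.020 to 0.43 in the other groups. The brown module of 1296 genes holds 16 of the 20 homeostatic genes (Fisher's exact test, adjusted p = 1.11e-09) and 18 of the 35 lysosomal genes (adjusted p = 7.78e-07). Its standardized score was -0.45 ± 0.23 in wildtype PBS (n = 9) and 0.19 ± 0.25 after 1xLPS (n = 9), a difference of 0.64 in an exact two-sided permutation test (adjusted p = 0.0013), higher in 9 of 9 libraries. The brown score was also higher after 4xLPS in wildtype (0.49, exact adjusted p = 0.00324) and in APP23 PBS against wildtype PBS (0.57, exact adjusted p = 0.00135), in 6 of 6 libraries each; with only the 10 genes of membership 0.8 or more the call after 4xLPS was lost (a difference of 0.96, adjusted p = 0.161). The yellow module of 878 genes holds 12 of 18 antigen presentation genes (adjusted p = 6.82e-08) and 9 of 24 interferon genes (adjusted p = 0.00296). Its score fell after 1xLPS (-0.46, exact adjusted p = 0.0013) and 4xLPS (-0.58, exact adjusted p = 0.00045) in wildtype mice. It was lower in APP23 PBS (-0.37, exact adjusted p = 0.00749) and higher in APP23 than in wildtype after 1xLPS (0.54, exact adjusted p = 0.00899). The red module of 733 genes, with the highest median gene significance in the authors' deposited table (0.237), was higher after 4xLPS than PBS in wildtype mice (0.75, exact adjusted p = 0.00045) and in APP23 than wildtype after 1xLPS (0.75, exact adjusted p = 0.00225). The pink module of 447 genes rose after 1xLPS (0.61, exact adjusted p = 0.00148) and 4xLPS (0.97, exact adjusted p = 0.00045) in wildtype mice. In APP23 PBS against wildtype PBS, pink (0.75, exact adjusted p = 0.00135) and red (0.62, exact adjusted p = 0.00135) were higher and turquoise lower (-0.44, exact adjusted p = 0.00749). The green module of 792 genes was higher in APP23 than in wildtype microglia after PBS (0.675, exact adjusted p = 0.00135), 1xLPS (0.62, exact adjusted p = 0.00225) and 4xLPS (0.54, exact adjusted p = 0.0429). With only its 2 genes of membership 0.8 or more the call after 1xLPS was lost (a difference of 0.91, adjusted p = 0.0629) and that after 4xLPS kept (1.74, adjusted p = 0.019). The latter was lost with the median as score (0.55, adjusted p = 0.0643). The magenta module of 292 genes, with 9 of 17 proliferation genes (adjusted p = 1.59e-08), passed in no contrast.

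Of 81 module tests 22 passed, and none of these was among the 3 contrasts within APP23, where the smallest exact adjusted p was 0.0714, for red between 4xLPS and 1xLPS. With 126 splits in that contrast, the exact p could not be smaller than 0.00794, the value for red. A module alone at this limit has an adjusted p of 0.0714, so the test could not call it whatever its difference. With the median of a module's genes as its score 22 passed too, and red was then higher after 1xLPS than PBS in APP23 mice (0.365, 5 of 5 libraries, adjusted p = 0.039, against 0.0779 by the mean). Because the table was corrected with the group means kept, these permutation p-values are too small by an unknown amount. With only genes of membership 0.8 or more, 5 of 18 tests that could be made passed.

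**Figure D4:**
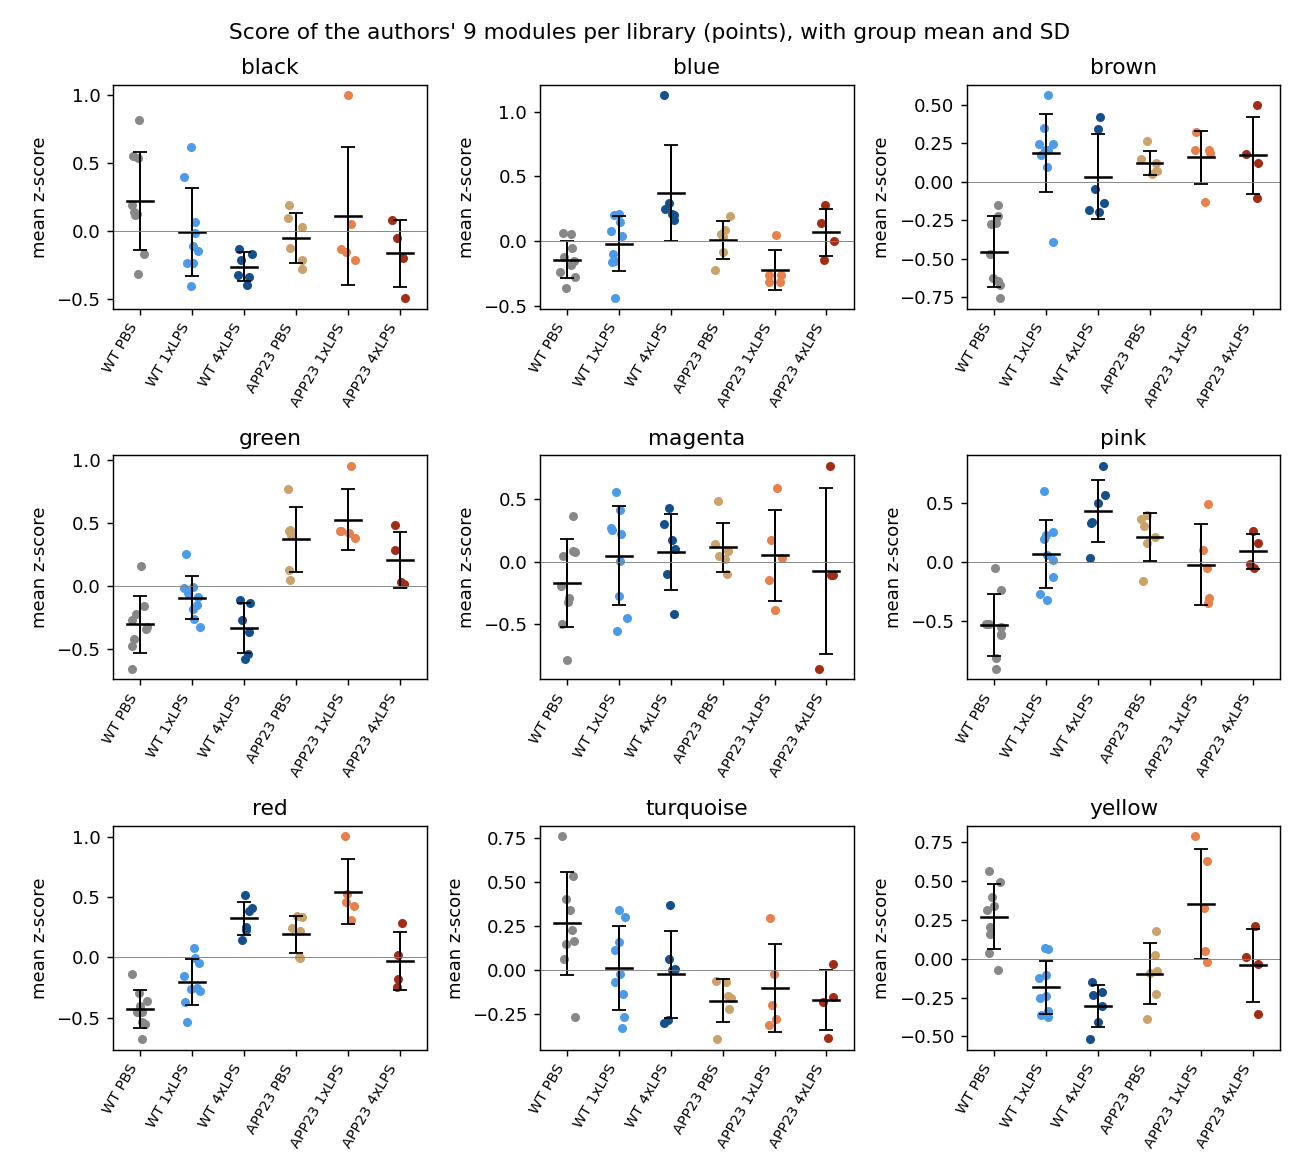
Score of each co-expression module (vertical axis, mean standardized expression of its genes, no unit) in each library of the 6 groups (horizontal axis), with points for libraries and bars for the group mean and SD. The pink score lies at -0.535 in wildtype PBS and 0.43 in wildtype 4xLPS.

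Across genes, the changes after 1xLPS and 4xLPS in wildtype mice correlated at r = 0.635 (rho = 0.611, over 10915 entries, which are not independent replicates). Both share the PBS libraries, and unchanged groups simulated against those gave a mean r of 0.408 with a 95% range of -0.00849 to 0.687, which holds the observed value. The covariance was 0.000731 against a simulated 0.000238 (upper end of its 95% range 0.00048). With the PBS libraries split between the contrasts the median r was 0.412, against a mean of 0.16 and a highest value of 0.263 in 20 simulated tables without effects, corrected for hidden factors drawn at random. Simulations that also kept the correlation between genes reached 0.556, with 4 of 100 as large as the observed r (7 with libraries drawn with replacement), and without kept group means 0.279, with 0 as large (0.27 and 0 with replacement). They shared 138 risers and 106 fallers, against 18.5 and 11.4 for independent lists. Lists of the same sizes from unchanged groups with shared controls had 83 (95% range 12.5 to 167) and 57.2 (5.95 to 131) in common, ranges that hold the observed overlaps, and the 20 tables corrected for random factors had at most 117 and 92. In APP23 mice the r between 1xLPS and 4xLPS was 0.357 (rho = 0.323) against a simulated 0.415 (0.0742 to 0.723), the covariance 0.000421 against 0.00039, and the r with split controls 0.0958 against a simulated mean of 0.16. They shared 2 risers and 1 faller, against 0.0618 and 0.0363 for independent lists and 1.36 and 0.73 in unchanged groups with shared controls. Across genotypes, where no library is shared, the changes correlated at r = -0.0651 (rho = -0.0595) for 1xLPS and r = -0.142 (rho = -0.136) for 4xLPS, with simulated ranges of -0.392 to 0.405 and -0.377 to 0.345. The 1xLPS contrasts shared 1 riser and 0 fallers across genotypes, against 1.5 and 0.892 for independent lists, and the 4xLPS contrasts 0 and 1, against 0.761 and 0.465.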

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

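The tests on macrophages and dendritic cells, the correlations and overlaps of the wildtype LPS contrasts with the genotype contrast, and the simulations that kept the correlation between genes were chosen only after the result was seen.

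The mean of 6 MHC class II genes picked for this pattern was lower in APP23 PBS than in wildtype PBS microglia, a difference of -0.197 (95% interval -0.258 to -0.136), and H2-Aa, H2-Ab1, H2-Eb1 and Cd74 passed but H2-DMa (-0.023) and H2-DMb1 (-0.0087) did not. Fewer perivascular or meningeal macrophages in the sorts cannot be told apart from a change within microglia: the 7 macrophage markers differed by a mean of -0.00182 (-0.0396 to 0.0359, exact p = 0.918, adjusted p = 0.918), but 3 were lower and the others higher (Mrc1 -0.12, Stab1 +0.067), and the most abundant, Stab1 (12.96) and Maf (10.46), may also be made by microglia. A smaller share of dendritic cells is a candidate explanation: 7 of 8 markers had negative differences, with a mean of -0.0423 over all 8 (-0.0825 to -0.00204, exact p = 0.0412), too small by an unknown amount since group means were kept, which fails correction over the 4 list tests (adjusted p = 0.0823); the most abundant of the 8, Itgae (8.86), differed by +0.043, Plbd1 by -0.14 and Batf3 by -0.039, and the microglial sort would be meant to remove such cells. Within groups the class II mean followed the macrophage list (r = 0.378, rho = 0.38, permutation p = 0.019 and 0.0247, adjusted p = 0.038, and r = 0.371 without 2 libraries) and the dendritic list (r = 0.359, rho = 0.335, permutation p = 0.0438 and 0.0613, adjusted p = 0.0438, and r = 0.415 without 2 libraries) over 39 libraries. These permutation p-values are too small by an unknown amount as well, because the residuals span fewer directions than the libraries allow. They do not establish that the lists vary together, and a varying share of other cells stays open. A genotype effect on microglia themselves stays open too and was untested, as does sequencing by genotype. A varying share of monocytes was not tested in this way. The monocyte marker Ccr2 was lower (-0.23, limma adjusted p = 0.00303), while its list of 5 measured genes did not pass (camera adjusted p = 0.406).

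Fos, Per1 and Ddit4, picked for this pattern from genes called in this contrast, were higher in APP23 PBS than in wildtype PBS microglia, by a mean of 0.219 (0.156 to 0.281). This interval describes the pattern and does not test it. A different clock phase at isolation cannot be told apart from other causes: evening minus morning genes differed by -0.0321 (-0.116 to 0.0518, exact p = 0.422, adjusted p = 0.562), with members going both ways (Arntl -0.11, Clock +0.094). Glucocorticoid exposure before isolation is a candidate explanation, since 5 genes induced by it were higher by a mean of 0.0441 (0.0123 to 0.0758, exact p = 0.0102, adjusted p = 0.0408), in 4 of 5 genes, with Sgk1 at 0.053 (adjusted p = 0.0665 with 24 degrees of freedom) and Fkbp5 at 0.10 (adjusted p = 0.0718, not called). This is smaller than the rise of the 3 genes, its exact p is too small by an unknown amount because the table was corrected with group means kept, and handling, isolation order, sequencing by genotype and the genotype itself stay open, untested. Per1 was also higher in wildtype 1xLPS and 4xLPS than in the same wildtype PBS libraries, calls that were lost with 24 degrees of freedom. Its higher level against wildtype PBS was thus not particular to APP23 PBS microglia.

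Wildtype 1xLPS and 4xLPS microglia differed from wildtype PBS in the same direction as APP23 PBS microglia did: r = 0.63 (rho = 0.603) and 0.612 (rho = 0.594) across genes, with 157 and 198 shared risers (19.6 and 29.8 for independent lists) and 96 and 131 shared fallers (12.5 and 17.9). The shared wildtype PBS libraries alone gave a simulated r of 0.443 (95% range 0.0938 to 0.761) and 0.35 (-0.0259 to 0.629), 94.3 (25.5 to 194) and 102 (23.9 to 199) shared risers and 67.2 (14 to 152) and 67.8 (13.9 to 136) shared fallers, ranges that hold each observed value, and covariances of 0.000258 and 0.000233 (upper ends of the 95% ranges 0.000603 and 0.000517) against an observed 0.00075 and 0.000878. In 20 tables of unchanged, independent genes corrected for random factors the highest r was 0.616 and 0.517, with at most 146 and 154 shared risers and 114 and 119 shared fallers, which all observed values but 96 exceeded. With separate control libraries the median r was 0.414 and 0.435, above the bound set beforehand (0.337 and 0.334, highest of those tables), but that bound was wrong for genes that vary together: 100 simulations that kept their correlation and the group means reached 0.525 and 0.408 (2 and 0 as large; 0.449 to 0.51 and 0.393 to 0.492 in 4 further sets of draws, with 2 to 5 and 0 to 3 as large), or 0.537 and 0.574 with libraries drawn with replacement (11 and 3), and without kept group means 0.263 and 0.226 (0 and 0), or 0.52 and 0.479 with replacement (2 and 1). So the shared controls, with the authors' correction, cannot be told apart from a common change after LPS and in the APP23 genotype, which stays open and was untested.

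The response to LPS differed between the genotypes by an interaction test in 370 genes for 1xLPS and 579 for 4xLPS, and in 4 and 57 with 24 degrees of freedom. Both interactions use the same PBS groups. There the genotypes differed in Fos (0.27), Cd74 (-0.26) and H2-Aa (-0.33), opposite in sign to the 1xLPS interactions. For Cd74, Rhob and Psap the PBS difference nearly equalled the 1xLPS interaction in size, which leaves little genotype difference after 1xLPS. The interaction test alone does not show whether the PBS or the LPS groups account for an interaction. The antigen presentation list (median 0.0332) and the immediate early list (median -0.081) passed camera for 1xLPS, but not with an estimated correlation (adjusted p = 0.606 and adjusted p = 0.539). For 1xLPS the interactions, of which none named here passed with 24 degrees of freedom, were positive in Als2cl (0.281), Kctd12b (0.263), Cd74 (0.26), H2-Aa (0.254), H2-Eb1 (0.219) and H2-D1 (0.084) and negative in Fos (-0.402), Osbpl3 (-0.288), Xkr8 (-0.219), Fpgt (-0.214), Mtor (-0.191), Rhob (-0.113) and Psap (-0.106). For 4xLPS the interactions were positive in Lpl (0.324), Dock9 (0.303), St8sia4 (0.281), Mrc2 (0.276), Hmgcs1 (0.174), Sqle (0.141), Srebf2 (0.116) and Ctsh (0.0674) and negative in Fos (-0.28), Sdr42e1 (-0.272), Tmem110 (-0.249), Zfp169 (-0.247), Ms4a7 (-0.194) and Chuk (-0.104), of which Dock9, St8sia4, Sdr42e1 and Tmem110 passed with 24.

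The number of genes called was set beside other splits of the same libraries into groups of the same sizes, 100 per contrast with the real split included. The real split had the highest count, 1 of 100, in each of the 11 contrasts: 660 in wildtype 1xLPS against PBS (highest other 91), 977 in wildtype 4xLPS against PBS (75), 78 in APP23 1xLPS against PBS (17), 27 in APP23 4xLPS against PBS (8), 72 in wildtype 4xLPS against 1xLPS (21), 162 in APP23 4xLPS against 1xLPS (80), 1050 between genotypes after PBS (114), 474 after 1xLPS (130), 171 after 4xLPS (25), 370 for the 1xLPS interaction (54) and 579 for the 4xLPS interaction (100). This test was void: a correction that keeps group means favours the real split, which came out on top in 9 or 10 of 10 simulated tables without any effect, with up to 261 of 3000 genes called. It therefore neither excludes chance nor shows that chance could not be excluded.

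In 61 of 1062 group and measure combinations 1 library lay far from the others of its group, where chance gives about 1 in 20. Values are log2 expression or module scores, each high or low for its group. Wildtype 4xLPS replicate 3 had 6 such values. In wildtype PBS, replicate 1 had high Mrc2 (10.9) and low Sema4a (8.72), and replicate 5 had high Abcg1 (10.9). There, replicate 7 had high Srebf2 (9.45) and low Fos (8.81), and replicate 9 had low Clec7a (9.54). In wildtype 1xLPS, replicate 1 had low Tlr4 (11.7), and replicate 2 had high Dock9 (10.3) and low Dusp1 (8.65). There, replicate 5 had low brown module score (-0.391) and Tyrobp (10.8), and replicate 6 had low Scarb2 (11.1). There, replicate 8 had low Banp (9.66), and replicate 9 had high H2-K1 (10.9). In wildtype 4xLPS, replicate 1 had high Stat2 (10.6), and replicate 2 had high Fam199x (9.32) and low Kctd12b (8.46), Sema4a (8.9) and Ubn1 (10.3). There, replicate 3 had high Ccl3 (8.92) and Zfp595 (8.64) and low Cd74 (10.6), Cox7b (8.14), Ddit4 (7.49) and Mtor (9.97), and replicate 4 had high blue module score (1.13) and low Pdp1 (8.25). In APP23 PBS, replicate 1 had high Zfp738 (9.27) and low App (10.9) and Ncoa2 (10.7), and replicate 2 had high Banp (9.92) and low Zfp595 (8.3). There, replicate 3 had low H2-K1 (10.8), and replicate 4 had high Rab3ip (9.3) and Rtp4 (9.44). There, replicate 5 had low Spp1 (6.97), and replicate 6 had high Axl (10.3). In APP23 1xLPS, replicate 1 had high blue module score (0.0502), green module score (0.954), Sema4a (9.08) and Xrcc2 (8.32), and replicate 2 had high Rpl19 (4.41), Xkr8 (8.87) and Zfp783 (8.54) and low Zfp456 (8.61). There, replicate 3 had high H2-D1 (11.2) and Nlrc5 (9.64), and replicate 4 had high black module score (1) and low Senp8 (9.28) and Slc27a4 (8.81). There, replicate 5 had high Ncoa2 (10.8) and low Ubn1 (10.3). In APP23 4xLPS, replicate 1 had high Cadm1 (10.9), and replicate 2 had high Fcgr2b (10.8) and Phka1 (9.98) and low Tnf (6.99). There, replicate 3 had high Hipk2 (9.02), and replicate 4 had high Ticam2 (10.8) and low Klf10 (9.15), Slc27a4 (9.05) and Slc2a3 (8.18).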

How the results depend on the processing

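The camera test with the 9 directions as covariates was the only one of these tests chosen after the result was seen. The table had been corrected in a way that kept group means, and no alternative here restores what was removed, and in simulated tables a larger share of the calls was false with 33 degrees of freedom than with 24. Sequencing depth, lanes and separate animals were not given in the sources used here, and the smallest groups held 4 and 5 libraries. No pseudocount alternative applied to a log table. No called value reversed its direction in any alternative, and the cause of a changed count was not tested unless given.

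With only the genes above the median mean level, and so fewer genes tested, calls numbered 364 in wildtype 1xLPS and 500 in wildtype 4xLPS against PBS, 38 and 5 in APP23, 84 in APP23 4xLPS against 1xLPS, 589, 258 and 94 between genotypes after PBS, 1xLPS and 4xLPS, and 166 and 325 for the interactions. With 24 degrees of freedom, where fewer are left by construction, the calls were 48 and 165 in wildtype against PBS, 2 in wildtype 4xLPS against 1xLPS, 274, 36 and 0 between genotypes, 4 and 57 for the interactions, and 0 in each of APP23 1xLPS against PBS, 4xLPS against PBS and 4xLPS against 1xLPS (limma, with 924, 832 and 1063 genes at unadjusted p under 0.05); 173 of 371 named calls were lost and lists called between genotypes after PBS numbered 4 in place of 2. With only the groups of the contrast, and so fewer libraries, limma called 27 and 0 in APP23 1xLPS and 4xLPS against PBS, 2 in APP23 4xLPS against 1xLPS, 32 in wildtype 4xLPS against 1xLPS and 0 between genotypes after 4xLPS (the counts of 0 had 1197 and 1478 genes at unadjusted p under 0.05). Of 371 named calls this fit lost 87, the replicate block 55, quantile normalization 21 and the fit without a variance trend 7. Quantile normalization gave 283 higher and 314 lower genes in wildtype 1xLPS against PBS (365 and 295 in the main fit), 515 and 541 between genotypes after PBS (587 and 463) and 291 and 287 for the 4xLPS interaction (258 and 321).

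With the replicate block, calls numbered 3 in APP23 4xLPS against PBS, 34 in wildtype 4xLPS against 1xLPS and 104 between genotypes after 4xLPS, where the cholesterol list was called (adjusted p = 0.0459). Between genotypes the homeostatic list after PBS (adjusted p = 0.0713) and the lysosomal list after 1xLPS (adjusted p = 0.0661) were not called with it, and the interferon list after PBS was (adjusted p = 0.0384). In the corrected values same-numbered libraries showed little likeness. Over 79 same-numbered pairs across groups the median r of residuals was 0.0359 (-0.378 to 0.283), and 17 were over 0.1. Other pairs had a median of -0.00151, and 3 of 39 libraries correlated best with their own number. Any likeness of paired libraries could have been taken out with the variation removed from the table. Whether the numbers pair the libraries therefore stays open.

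With an estimated correlation camera called 0 lists (smallest adjusted p = 0.168) in wildtype 1xLPS, APP23 1xLPS and APP23 4xLPS against PBS, in APP23 4xLPS against 1xLPS, between genotypes after PBS and 1xLPS, and for the 1xLPS interaction. Fry called 0 lists in wildtype 1xLPS and 2 in wildtype 4xLPS against PBS, 0 in APP23 4xLPS against PBS and 1 in APP23 4xLPS against 1xLPS. Between genotypes it called 3 after PBS and 2 after 1xLPS, but only 1 of the 2 and 1 of the 3 lists called there by camera. It kept 3 of 4 lists in APP23 1xLPS against PBS and 2 of 2 for the 1xLPS interaction. Of the module tests, 5 of 18 passed with genes of membership 0.8 or more, against 22 of 81, and by the median 22 of 81 passed, with green between genotypes after 4xLPS lost (adjusted p = 0.0643). With split controls the r between 1xLPS and 4xLPS was 0.412 in wildtype and 0.0958 in APP23 mice.

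Leaving out each APP23 LPS library in turn gave 23 to 87 calls in APP23 1xLPS and 7 to 32 in APP23 4xLPS against PBS, 49 to 171 in APP23 4xLPS against 1xLPS, 238 to 507 and 53 to 170 between genotypes after 1xLPS and 4xLPS, and 222 to 391 and 365 to 572 for the interactions. Fewest calls came without APP23 1xLPS replicate 1 (23) or 4 (49, 238, 222) and without APP23 4xLPS replicate 3 (53, 365) or 4 (7), and 300 of 1953 named calls were lost over all of these fits.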

Other observations

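Of the tests in this part, the correlation of deposited gene significance with group membership was chosen only after the result was seen.

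Apoe, Trem2, P2ry12, Tmem119 and Cx3cr1, which are often followed in plaque-bearing mice, were called in none of the 11 contrasts, while Cst7 was called in all 3 comparisons of the genotypes, at 0.14 after PBS (adjusted p = 0.0416), 0.25 after 1xLPS (adjusted p = 0.00248) and 0.20 after 4xLPS (adjusted p = 0.0483), of which only that after 1xLPS passed with 24 degrees of freedom (adjusted p = 0.14, 0.0426 and 0.254). Cst7 levels were 8.68 ± 0.092, 8.635 ± 0.0535 and 8.58 ± 0.077 in wildtype PBS, 1xLPS and 4xLPS (SD, n = 9, 9 and 6) and 8.82 ± 0.074, 8.88 ± 0.10 and 8.78 ± 0.15 in APP23 (n = 6, 5 and 4). Psap was at 12.12 ± 0.026 in wildtype PBS and between 12.19 and 12.24 in each of the other 5 groups.

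The deposited gene significance followed the correlation with APP23 1xLPS membership at r = 0.986 across genes, and its median was highest in the red (0.237) and green (0.204) modules and lowest in blue (-0.103) in the authors' deposited table.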
